A study of Mus musculus with 8 samples.

How the data were processed

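Total RNA from 8 samples of 250000 ATCL7 cells each was labelled from 250 ng and hybridised to Affymetrix Mouse Gene 1.1 ST array strips, 1 array per sample. The titles give 4 BIO and 4 vehicle samples and put them in 4 numbered pairs. Cells were grown with 2.5% each of 2 sera and treated in medium with 0.025% of each, per the labels' protocols.

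The authors deposited log2 values made with RMA (background correction, quantile normalization and summary per probe set, from perfect-match probes only), with the oligo package, per the submitters' processing notes and the file headers. The oligo version is not given in the sources used here. Because RMA compresses low signals, fold changes of dim genes are understated. Values ran from 2.25 to 13.02 log2 over 28944 probe sets, with no detection call and no scanner files used here, so which dim probe sets lie above background is unknown. Per the file headers, rows were limited by the authors to 3 of the manufacturer's probe set categories and annotated from Bioconductor. The authors' second table repeats the per-array values (largest difference 5.0e-09 log2) and adds the authors' p-values of a paired t-test, not adjusted, and the average fold change as a ratio of BIO over vehicle. It also gives the authors' p-values and fold ratios of another experiment, used as deposited.

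Gene symbols came from the deposited annotation. Of the probe sets, 23812 had 1 symbol, 5132 had none and 0 had several. Gene identifiers matched the RefSeq gene table of assembly GRCm38.p6 for 20480 genes and failed to match for 239, and 1875 symbols were updated. The table was used for names only, and no coordinates are given because the genome build of the annotation is not given in the sources used here. For each of the 20719 genes the probe set with the highest mean over all arrays was used, and 1683 genes had more than 1.

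Arrays correlated at 0.9948 to 0.9986 within groups and 0.988 to 0.992 between them across genes, which are not independent replicates. No array duplicated another. Differential expression was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 as BIO minus vehicle with the pair as a block, two-sided, with Benjamini-Hochberg adjustment over the 20719 genes and a threshold of 0.05. Moderated degrees of freedom were 8.07. The pairing comes from the titles. As a check, the deviations of same-numbered arrays from their group means correlated across genes at 0.446, 0.578, 0.385 and 0.617, all above 0.1. Vehicle replicate 3 correlated slightly more with BIO replicate 4 (0.392). Differently numbered arrays also correlated within pairs 1 and 2 (0.243 and 0.284) and for vehicle replicate 4 with BIO replicate 3 (0.277). Across these 2 blocks all correlations lay between −0.504 and −0.214. The check thus sets pairs 1 and 2 apart from pairs 3 and 4, and does not by itself establish the pair numbers. In an exact sign-flip test of a single gene 4 pairs allow no two-sided p under 0.125, so calls rest on a model of the spread. Limma shares that spread across genes. The authors' paired t-test uses each gene's own, and after Benjamini-Hochberg adjustment it passed 3705 of the 6767 genes that limma called.

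In all, 17 gene lists with 318 entries, 316 of them measured, were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. Of the 17 lists, 12 passed with the preset correlation, 0 with the estimated correlation (5 at an unadjusted p under 0.05) and 16 with fry. The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 greatest rises and the 10 greatest falls among genes past the threshold with the same direction in 4 of 4 pairs, leaving out predicted gene models, up to 4 members of each list past the threshold with the largest change, 14 fixed genes, and members named to show values that did not pass; genes outside it are marked in the text as named after their values were seen. Some genes that the rule selects are not reported here. Of the 14 fixed genes, Ccdc80 was included from knowledge of the authors' work. Lists of tRNA synthetases and of NRF2, MiT/TFE and FoxO targets were written after the main results were known and before their own values were seen.

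The procedure was tested on simulated data for BIO against vehicle in 4 pairs, 5 runs of 20719 genes with 200 changed in each. It recovered 46.8% of genes changed by 0.3 log2, 90.8% at 0.585, 97.2% at 1 and 100% at 2, and 2.9% of calls were false. In the real data 32.7% of genes passed, a far larger share than was changed in the simulation. The Benjamini-Hochberg cutoff depends on the share that passes and was stricter in the simulation. The recovered shares therefore do not carry over to the real comparison. Camera called 0 of 85 unchanged lists, and called a list lowered by 0.3 log2 in 5 of 5 runs. The simulated noise was drawn independently for each gene, whereas correlations estimated for the real lists reached 0.399. False list calls from genes that vary together were therefore not tested.

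Alternatives covered the pair block, the eBayes prior, filters on the lowest 25% and 50% of genes, array medians, quantile and cyclic loess normalization, the mean of a gene's probe sets, every probe set, array weights, the deposited second table, each pair left out and the authors' p-values. The methods' t-test, as the authors deposited its p-values, passed 7388 genes at an unadjusted p of 0.05 and 3947 after Benjamini-Hochberg adjustment. Other tests used scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A plotting sheet that repeats 2 genes was not used here.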

Results

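Gene expression was measured in ATCL7, an immortalized cell line from a mouse adrenocortical tumour, after 24 h in low-serum medium with 0.5 µM BIO or with 0.01% DMSO as vehicle. BIO is a brominated indirubin oxime used as an inhibitor of glycogen synthase kinase 3, the kinase that marks β-catenin for degradation, and indirubins are also known ligands of the aryl hydrocarbon receptor. The series addresses Wnt/β-catenin signalling in these cells. The 8 samples formed 4 numbered pairs, each with 1 BIO and 1 vehicle sample, and each sample was read on 1 Mouse Gene ST array. The median log2 value lay between 5.7 and 5.73 on all 8 arrays, and the number of arrays limits the precision. A deposited plotting sheet calls each pair an experiment, but the labels do not say that the pairs were separate cultures, so p-values measure only the spread between these samples, which may be partly technical. The array numbers in the labels run through the 4 BIO arrays first and the 4 vehicle arrays after them, and strip and scan batch are not given in the sources used here, so no batch could be tested.

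BIO changed the expression of a large share of the genes. Of 20719 genes, 3531 rose and 3236 fell. The greatest rises by the fixed rule were those of B4galnt2, a glycosyltransferase, from 4.95 ± 0.15 to 8.76 ± 0.77 log2 (mean ± SD, n = 4 arrays each), P2rx3, an ATP-gated ion channel, from 5.79 ± 0.19 to 9.26 ± 0.48, and Axin2, the feedback inhibitor of the Wnt pathway, from 6.13 ± 0.07 to 9.14 ± 0.12. These are 14.0-fold, 11.1-fold and 8.09-fold rises. The greatest falls were those of Akr1c18, a reductase that inactivates progesterone (19.4-fold lower), Anxa8, an annexin (15.4-fold lower), and Spp1, which encodes osteopontin (11.2-fold lower). The log2 changes were 3.81 ± 0.21 (SE) for B4galnt2, −4.28 ± 0.11 for Akr1c18, −3.94 ± 0.18 for Anxa8 and −3.49 ± 0.19 for Spp1, with limma adjusted p of 8.36e-06, 2.62e-07, 3.39e-06 and 8.31e-06.

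The other genes among the 10 greatest rises were Cox6a2, a cytochrome c oxidase subunit of muscle (log2 change 2.90), Slc7a11, a cystine transporter (2.53), Trib3, a stress-induced pseudokinase (2.24), Ahrr, the repressor of the aryl hydrocarbon receptor (2.13), Ccdc80, a secreted matrix protein (2.12), Igsf11, an adhesion protein (2.09), and Angptl6 (1.95). Those among the 10 greatest falls were Dab1, an adaptor of reelin signalling (−3.07), Map3k7cl (−2.79), Rgs4, a regulator of G protein signalling (−2.74), Ctla2a (−2.73), Dkk1, a secreted Wnt inhibitor (−2.69), Grin2a, a glutamate receptor subunit (−2.56), and Cxcl12, a chemokine (−2.48). The rule took only genes that moved the same way in 4 of 4 pairs, so the agreement of these 20 is no result. The limma adjusted p of the 20 genes ranged up to 4.59e-05. Ccdc80 was on the list of genes to report because the authors of the series are known to have studied it, so its rise from 7.06 ± 0.36 to 9.19 ± 0.17 log2 (SD, n = 4) is not independent evidence. Igsf11 and Ahrr each had 1 BIO array that stood apart from the other 3. The log2 changes in pairs 1 to 4 were 2.112, 2.252, 2.108 and 1.904 for Igsf11. For Ahrr they were 2.462, 2.047, 2.062 and 1.96.

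Across the 20719 named genes, 6767 (32.7%) passed an adjusted p of 0.05 in limma with the pair as a block, 3531 of them higher in BIO and 3236 lower. Of these, 454 were at least 1.5-fold higher and 684 at least 1.5-fold lower, and 89 and 231 were at least 2-fold higher and lower. The direction was the same in 4 of 4 pairs for 47% of all genes, against 12.5% by chance. It was the same for 98.5% of the 6767 genes, which a call in the paired fit itself favours. The median log2 change over all genes was −0.01, and the median SE of a log2 change was 0.05. When the genes were ranked by mean value and divided into 4 equal parts, 4.4%, 22.4%, 57% and 46.8% passed from the dimmest part to the brightest. The p-values of the authors' own paired test, adjusted over the same genes, passed 3947 genes, 2057 higher and 1890 lower.

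Target genes of Wnt/β-catenin signalling moved in both directions. Of 26 measured members of the list, 9 rose, 11 fell and 6 did not pass; adjusted over the list alone, 9 rose and 13 fell. Axin2 rose most (log2 change 3.02 ± 0.07, SE, adjusted p = 2.22e-07), followed by Tnfrsf19, a receptor of the tumour necrosis factor family (1.05 ± 0.11), Rnf43, a ubiquitin ligase that removes Wnt receptors (1.02 ± 0.09), Tcf7, a transcription factor of the pathway (1.01 ± 0.05), Sp5 (0.89 ± 0.08), Nkd1 (0.69 ± 0.11), Znrf3 (0.49 ± 0.05), Lgr5 (0.38 ± 0.05) and Lef1 (0.25 ± 0.06). Dkk1 fell most, from 7.42 ± 0.73 to 4.73 ± 0.09 log2 (SD, n = 4), and the others that fell included Bmp4, a secreted growth factor (−1.82 ± 0.04, SE), Apcdd1, a Wnt inhibitor at the cell surface (2.01-fold lower), Sox9, a transcription factor (−0.98 ± 0.05), Myc (−0.76 ± 0.07) and Ccnd1, which encodes cyclin D1 (−0.63 ± 0.08). The median log2 change of the list was −0.12, and camera did not call it (adjusted p = 0.303, and adjusted p = 0.397 with an estimated correlation); the median was −0.078 without replicate 2 and −0.34 over the 13 members left with the lowest 50% of genes left out. By fry, which asks whether the members move on balance in 1 direction without comparing them with other genes, the list was lower in BIO (adjusted p = 0.00886).

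Without the pair block the calls of Ccnd1 (adjusted p = 0.379) and Lef1 (0.122) were lost, and that of Lef1 was also lost without replicate 3 (0.0612) and by the authors' paired test (0.11), as was that of Nkd1 (0.0961). In vehicle, 1 array each of Nkd1 and Sox9 stood apart from the other 3. Rnf43, Tcf7, Sp5, Nkd1, Znrf3, Lgr5, Myc, Sox9 and Apcdd1 were named after their values were seen.

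**Figure D1:**
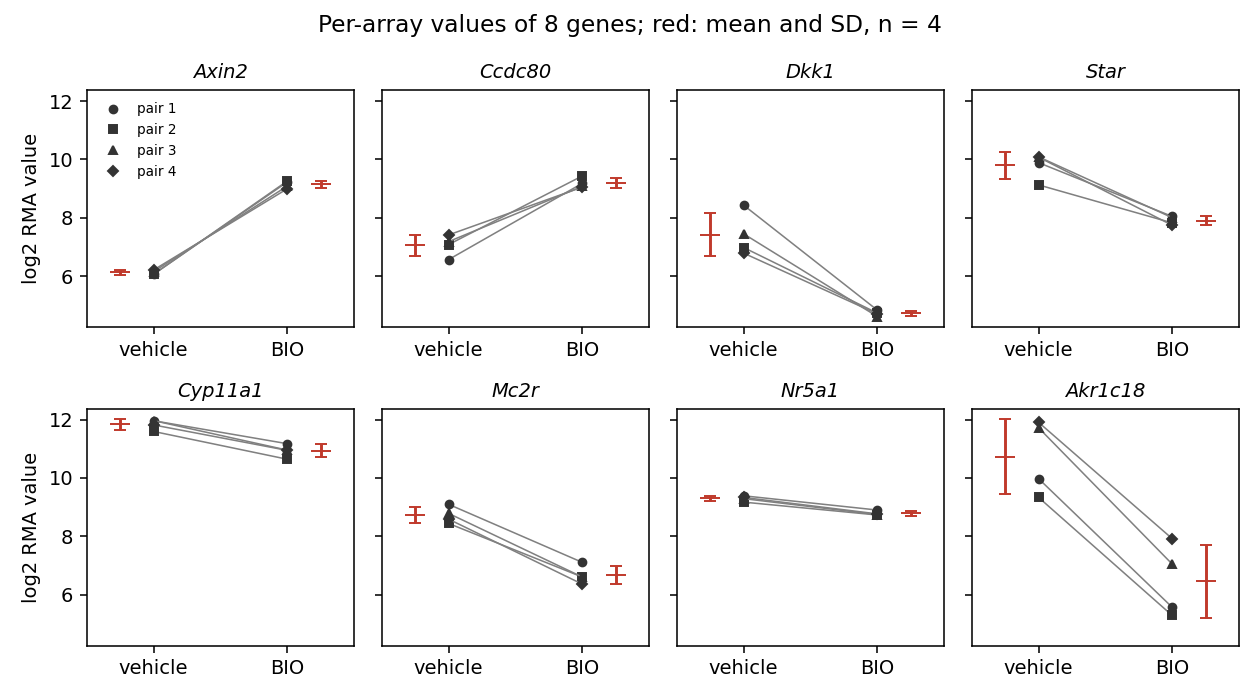
Log2 RMA values of 8 genes on each array, with vehicle on the left and BIO on the right of each panel. Each symbol is 1 array, grey lines join the 2 arrays of a pair, and red bars give the mean and SD of the 4 arrays. Axin2 and Ccdc80 were higher and the other 6 genes lower in BIO in all 4 pairs; the pairs lay far apart for Akr1c18 (SD 1.28 in vehicle) while its change was −4.28 ± 0.11 (SE).

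Most receptors and other components of the Wnt pathway did not pass. Of 35 measured members, 3 rose, 9 fell and 23 did not pass, with the same counts adjusted over the list alone. As 32.7% of all genes passed, a majority that did not pass is no trait of this list. The secreted inhibitors Sfrp4 (log2 change −2.02 ± 0.08, SE) and Sfrp2 (−0.97 ± 0.11) and the receptors Fzd8 (−1.35 ± 0.10) and Lrp6 (−0.51 ± 0.05) fell. Ctnnb1, which encodes β-catenin, was lower by 1.15-fold (−0.20 ± 0.05, adjusted p = 0.0125). Gsk3b, which encodes a kinase targeted by BIO, was at 9.94 ± 0.07 in vehicle and 9.95 ± 0.02 in BIO (SD, n = 4), a difference of 0.02 ± 0.04 (SE, adjusted p = 0.795) whose sign turned with cyclic loess normalization (−0.001). Camera did not call the list (adjusted p = 0.277, and adjusted p = 0.397 with an estimated correlation), while by fry it was lower in BIO (adjusted p = 0.00795). The call of Ctnnb1 was lost without replicate 3 (adjusted p = 0.0689) and by the authors' paired test (0.0667), which also lost that of Sfrp2 (0.0548).

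Genes of steroid hormone synthesis fell. Of 22 measured members, 14 fell, 1 rose and 7 did not pass, and these counts were unaltered when adjusted over the list alone. After Akr1c18, Mc2r, the receptor for adrenocorticotropic hormone, fell most, 4.16-fold from 8.73 ± 0.28 to 6.67 ± 0.31 log2 (SD, n = 4, adjusted p = 1.19e-06). Star, which carries cholesterol into mitochondria, was 3.71-fold lower (−1.89 ± 0.14, SE, adjusted p = 3.5e-05), Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, was 1.87-fold lower (−0.91 ± 0.05, adjusted p = 9.3e-06), and Hsd3b1 was 1.64-fold lower (−0.71 ± 0.16, adjusted p = 0.00845). Por, the electron donor of microsomal P450 enzymes, named after its value was seen, was the riser (0.20 ± 0.05, adjusted p = 0.0184). The median log2 change of the list was −0.43, and camera called it (adjusted p = 4.12e-06; adjusted p = 0.144 with an estimated correlation).

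Cyp21a1, Cyp17a1 and Cyp11b2, enzymes of corticosteroid, androgen and aldosterone synthesis, did not pass, with differences of −0.09, −0.12 and −0.11 log2 at vehicle means of 4.60, 4.03 and 4.22, and 1 BIO array of Cyp11b2 stood apart from the other 3. Akr1c14, a related reductase outside the lists that was named after its value was seen, was 5.07-fold lower (log2 change −2.34 ± 0.20, SE). The call of Hsd3b1 was lost without the pair block (adjusted p = 0.23) and by the authors' paired test (0.164). That of Por was lost in both as well (0.0817 and 0.0926) and without replicate 3 (0.0943) or 4 (0.0749).

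Transcription factors and signals of adrenal and gonadal identity changed in both directions. Of 22 measured members, 4 rose, 9 fell and 9 did not pass, and the counts were equal when adjusted over the list alone. Nr5a1, which encodes steroidogenic factor 1, was 1.42-fold lower (log2 change −0.51 ± 0.05, SE, adjusted p = 7.78e-05), and Nr0b1, which encodes DAX1, was 1.36-fold lower at a vehicle mean of 4.81 ± 0.27 log2 (SD, n = 4). Ptch1, the Hedgehog receptor, rose (0.73 ± 0.05, SE), with 1 BIO array apart from the other 3, as did Inha, which encodes an inhibin subunit (0.47 ± 0.09). Gata4 did not pass (0.05 ± 0.05). Camera did not call the list (median −0.08, adjusted p = 0.171, and adjusted p = 0.394 with an estimated correlation), while by fry it was lower in BIO (adjusted p = 0.0123). By the authors' paired test the calls of Nr0b1 (adjusted p = 0.13) and Inha (0.113) were lost.

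Genes of cholesterol synthesis and uptake, which are driven by the sterol-sensing factor SREBP2, also fell. Of 24 measured members 17 fell, 1 rose and 6 did not pass, and 17 fell and 2 rose adjusted over the list alone. Idi1, an isomerase of the pathway, was 1.69-fold lower (log2 change −0.76 ± 0.07, SE), Msmo1, a sterol oxidase, 1.62-fold (−0.69 ± 0.09) and Hmgcs1, a synthase at the start of the pathway, 1.58-fold (−0.66 ± 0.06). The median log2 change was −0.35, and camera called the list (adjusted p = 0.000118; adjusted p = 0.344 with an estimated correlation). The authors' paired test did not pass Msmo1 (adjusted p = 0.0661).

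Target genes of the aryl hydrocarbon receptor rose. Of 7 measured members of the 9 listed, 5 rose, none fell and 2 did not pass; 5 rose and 1 fell adjusted over the list alone. Ahrr rose 4.38-fold (log2 change 2.13 ± 0.08, SE), Cyp1b1, a P450 enzyme that oxidizes oestrogens, 2.98-fold (1.58 ± 0.12; a second, dimmer probe set rose by 0.89), and Tiparp, a polymerase that represses the receptor, 2.75-fold (1.46 ± 0.08). Cyp1a1, the classical target gene, rose 2.01-fold, from 3.79 ± 0.13 to 4.80 ± 0.37 log2 (SD, n = 4, adjusted p = 0.000966). Cyp1a2 and Aldh3a1 did not pass (−0.11 ± 0.05 and −0.12 ± 0.05, SE). The median log2 change was 1.01, and camera called the list (adjusted p = 0.00133; adjusted p = 0.178 with an estimated correlation), but with the lowest 50% of genes left out 2 members remained (median 1.518). The call of Cyp1a1 was lost by the authors' paired test (adjusted p = 0.0794), and 1 BIO array of Tiparp stood apart from the other 3.

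Genes of the unfolded protein and amino acid stress responses rose. Of 16 measured members, 13 rose, 1 fell and 2 did not pass, and 14 rose and 1 fell adjusted over the list alone. Slc7a11 rose 5.76-fold (log2 change 2.53 ± 0.07, SE, adjusted p = 5.37e-07), Trib3 4.74-fold (2.24 ± 0.07, adjusted p = 7.86e-07), Ddit3, a stress-induced transcription factor, 3.01-fold (1.59 ± 0.08) and Chac1, an enzyme that degrades glutathione, 2.97-fold (1.57 ± 0.05). The endoplasmic reticulum chaperones Hspa5 (0.14 ± 0.06, adjusted p = 0.0915) and Dnajb9 (0.19 ± 0.09, adjusted p = 0.144) did not pass, while Herpud1 (0.81 ± 0.07), Sdf2l1 (0.37 ± 0.05) and Xbp1 (0.36 ± 0.05), other genes of that organelle's stress response that were named after their values were seen, rose. The median log2 change was 0.67, and camera called the list (adjusted p = 4.96e-10; adjusted p = 0.144 with an estimated correlation). Hspa5 passed with an intensity trend and robust prior (adjusted p = 0.0214) and with the lowest 50% of genes left out (0.0484). Dnajb9 passed without replicate 4 (adjusted p = 0.0431), and its log2 changes in pairs 1 to 4 were 0.127, 0.533, 0.186 and −0.082. The call of Sdf2l1 was lost without the pair block (adjusted p = 0.062).

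**Figure D2:**
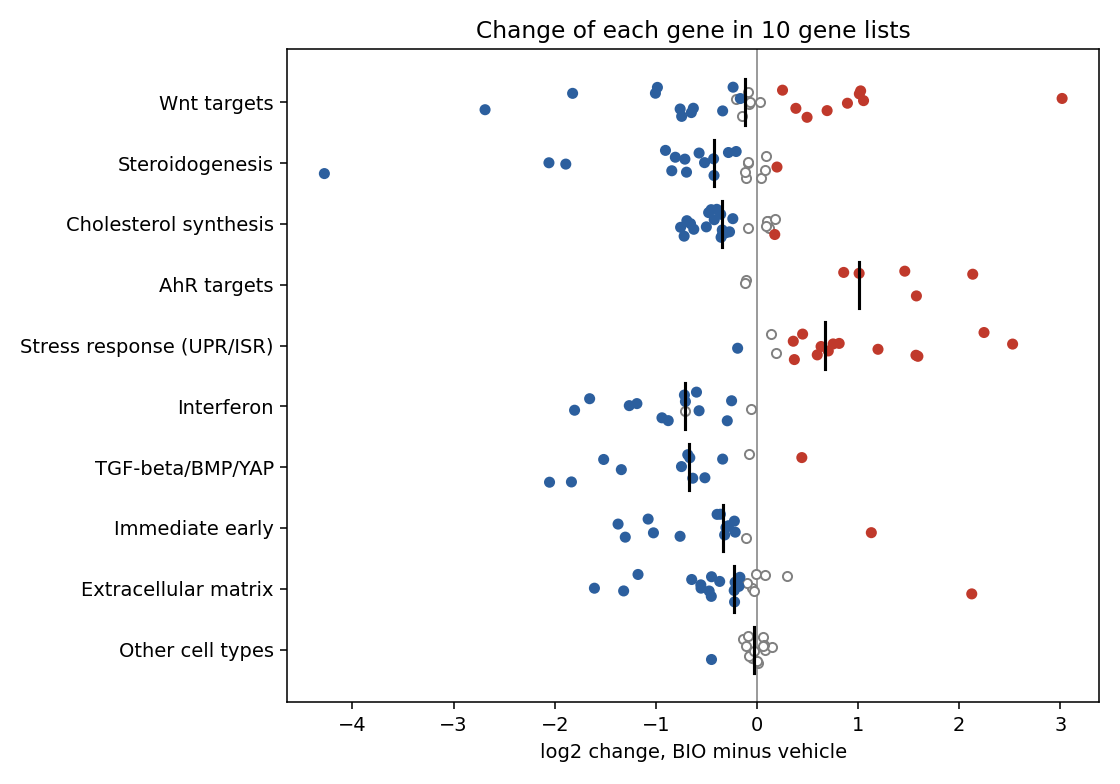
Log2 change, BIO minus vehicle, of each measured gene in 10 of the 17 gene lists. Each point is 1 gene (red, higher in BIO and past an adjusted p of 0.05; blue, lower and past it; open, not past it) and black bars give each list's median. The medians run from −0.72 for interferon-stimulated genes to 1.01 for targets of the aryl hydrocarbon receptor, and Wnt targets spread from −2.69 to 3.02.

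Most immediate early response genes fell, as did part of a list of Notch, Hedgehog and FGF/ERK targets. In the immediate early list, 12 of 14 members fell, 1 rose and 1 did not pass, also when adjusted over the list alone. Fos (log2 change −1.37 ± 0.11, SE), Egr1 (−1.30 ± 0.08) and Fosb (−1.08 ± 0.12), transcription factors induced within minutes of a stimulus, fell, and Atf3, which stress also induces, rose (1.13 ± 0.07). Camera called the list (median −0.34, adjusted p = 1.96e-05; adjusted p = 0.144 with an estimated correlation). In the list of Notch, Hedgehog and FGF/ERK targets, 8 of 16 members fell, 1 rose and 7 did not pass, and 10 fell and 1 rose adjusted over the list alone. Dusp6, a phosphatase of ERK, was 3.85-fold lower (−1.95 ± 0.11), the ERK-induced factors Etv5 and Etv4 were 2.43-fold and 2.38-fold lower, the Notch target Hes1 was 1.97-fold lower, and Ptch1 was the riser. Camera called this list as well (median −0.21, adjusted p = 0.000544; adjusted p = 0.144 with an estimated correlation), with a median of −0.473 over 14 members with the lowest 25% of genes left out and −0.86 over 6 with the lowest 50% left out. The call of Fosb was lost by the authors' paired test (adjusted p = 0.0517).

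Response genes of TGF-β, BMP and YAP signalling and genes of the extracellular matrix fell too. In the first list 10 of 12 members fell, 1 rose and 1 did not pass, also when adjusted over the list alone. Ankrd1, a YAP target, was 3.57-fold lower (log2 change −1.84 ± 0.10, SE), Ccn2, which encodes connective tissue growth factor, 2.86-fold (−1.52 ± 0.10) and Tgfbi 2.53-fold (−1.34 ± 0.09). Smad7 did not pass (−0.08 ± 0.06). Camera called the list (median −0.68, adjusted p = 3.53e-07; adjusted p = 0.144 with an estimated correlation). Of 22 matrix genes, 15 fell, 1 rose and 6 did not pass, and 15 fell and 2 rose adjusted over the list alone. Thbs1, which encodes thrombospondin, was 3.05-fold lower (−1.61 ± 0.05), Tnc, which encodes tenascin C, 2.5-fold (−1.32 ± 0.08) and Lox, a collagen cross-linking enzyme, 2.26-fold (−1.18 ± 0.05), while Ccdc80 was the riser. Camera called the matrix list (median −0.22, adjusted p = 2.49e-05; adjusted p = 0.206 with an estimated correlation), with a median of −0.452 over 13 members with the lowest 50% of genes left out.

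Interferon-stimulated genes and genes of hypoxia and glycolysis were lower in BIO. Of 14 interferon-stimulated genes, 12 fell, 0 rose and 2 did not pass, and 13 fell adjusted over the list alone. Ifit3 was 3.49-fold lower (log2 change −1.80 ± 0.08, SE), Ifit1 3.15-fold (−1.66 ± 0.15), Rsad2 2.4-fold (−1.26 ± 0.08) and Cxcl10, a chemokine, 2.28-fold (−1.19 ± 0.12). These genes differed strongly between pairs, with an SD of 1.09 log2 for Ifit1 and 1.26 for Cxcl10 over the 4 vehicle arrays, and without the pair block the calls of Ifit1 (adjusted p = 0.159), Ifit3 (0.0565), Rsad2 (0.22) and Cxcl10 (0.256) were lost. Ifi44 did not pass (−0.71 ± 0.25, adjusted p = 0.0648) but did with the lowest 50% of genes left out (0.0477) and without replicate 4 (0.0065), where its change was −0.30. Camera called the list (median −0.72, adjusted p = 6.41e-08; adjusted p = 0.144 with an estimated correlation).

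Of 14 genes of hypoxia and glycolysis, 11 fell, 2 rose and 1 did not pass, with the same counts adjusted over the list alone. Hk2, which encodes hexokinase, was 1.87-fold lower (log2 change −0.90 ± 0.09, SE), Bnip3, a mitophagy receptor, 1.69-fold (−0.76 ± 0.05), Slc2a1, a glucose transporter, 1.6-fold (−0.67 ± 0.05), and Egln3, an oxygen-sensing hydroxylase, 1.57-fold (−0.65 ± 0.05). Camera called the list (median −0.35, adjusted p = 8.62e-05; adjusted p = 0.275 with an estimated correlation). Without the pair block the call of Egln3 was lost (adjusted p = 0.0746).

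Cell cycle genes changed little in size, with mitotic and replication genes called in opposite directions. Of 20 genes of G2 and mitosis, 7 rose, 1 fell and 12 did not pass, and 8 rose and 1 fell adjusted over the list alone. Cenpe, a mitotic motor (log2 change 0.29 ± 0.05, SE), Birc5, which encodes survivin (0.24 ± 0.04), Bub1, a checkpoint kinase (0.23 ± 0.04), and Ube2c (0.21 ± 0.05) rose. Mki67, a proliferation marker, was at 11.07 ± 0.08 in vehicle and 11.11 ± 0.16 in BIO (SD, n = 4) and did not pass. Camera called this list (median 0.07, adjusted p = 0.00997; adjusted p = 0.394 with an estimated correlation), though not with the lowest 50% of genes left out (adjusted p = 0.0763). The call of Ube2c was lost without replicate 3 (adjusted p = 0.0813), without replicate 4 (0.0744) and by the authors' paired test (0.11).

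Of 21 genes of the G1/S transition and DNA replication, 10 fell, 1 rose and 10 did not pass, as they did adjusted over the list alone. Gins1, a subunit of the replicative helicase complex (log2 change −0.68 ± 0.04, SE), Mcm6, a helicase subunit (−0.50 ± 0.05), and Slbp, which binds histone mRNA (−0.29 ± 0.05), fell, Tyms, which encodes thymidylate synthase, rose (0.30 ± 0.05), and Pcna did not pass (−0.02 ± 0.05). Camera called the list (median −0.11, adjusted p = 0.00822; adjusted p = 0.275 with an estimated correlation). Slbp had a second probe set with a smaller fall (−0.18). Of 16 p53 targets, 2 rose, 5 fell and 9 did not pass, with identical counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.171, and adjusted p = 0.592 with an estimated correlation), except without replicate 3 (adjusted p = 0.0371). The risers Gadd45a (1.33 ± 0.16) and Sesn2 (1.20 ± 0.10) are also stress-induced, Fas (−0.55 ± 0.12) and Trp53inp1 (−0.50 ± 0.05) fell, and Cdkn1a (0.00 ± 0.05) and Mdm2 (−0.14 ± 0.07) did not pass. The authors' paired test lost the calls of Gadd45a (adjusted p = 0.0591) and Fas (0.147), and Mdm2 passed without replicate 3 (0.0483).

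Markers of cells that a cell line should lack, namely leukocytes, endothelium and chromaffin cells, mostly did not pass. Of 15 measured markers, 14 did not pass and 1 fell, also when adjusted over the list alone. The median level of the list was 4.49 log2. In the dimmest part of the genes ranked by mean value (median 3.86 log2) 4.4% passed, and in the next part (median 5.09) 22.4%. A majority that did not pass is therefore no trait of this list. It also does not test whether such cells were present. The faller was Cd68, a lysosomal protein of macrophages that other cells also make, from 7.70 ± 0.13 to 7.25 ± 0.11 log2 (SD, n = 4). Camera did not call the list (median −0.03, adjusted p = 0.574, and adjusted p = 0.592 with an estimated correlation), while by fry it was lower in BIO (adjusted p = 0.0227).

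The authors' deposited table also sets 3 arrays called Wnt against 4 called SF1 in another experiment, whose samples are not analysed here and whose groups are not explained in the sources used here. In the authors' deposited table, 376 genes had an unadjusted p under 0.05 and a change over 1.3-fold in both comparisons, of which 238 moved in the same direction and 138 in opposite directions (63.3% the same, Fisher's exact test, two-sided, odds ratio 3.16, p = 5.04e-07). The number lower in both was 159 against 57.9 for independent lists, and the number higher in both was 79 against 46.1, but 97 genes were lower in BIO and higher in Wnt, against 49.4, and 41 were higher in BIO and lower in Wnt, against 54.0 (Fisher's exact test, two-sided, adjusted p = 0.0622). Those 97 include 6 genes of the steroid list, Star and Cyp11a1 among them. By the authors' deposited table, whether or not they passed in BIO, 13 of the 22 listed steroid genes were higher in Wnt at an unadjusted p under 0.05 and 0 were lower, with folds of 2.04 for Star (p = 0.0122) and 2.00 for Cyp11a1 (p = 0.00728). Nr5a1 was 2.93-fold higher there (p = 0.00557), Ccdc80 was 1.5-fold higher (p = 0.0448) and Axin2 was at 1.59-fold (p = 0.216), by the authors' deposited table. Of the 26 Wnt targets, 3 were higher and 0 lower at that p in the authors' deposited table. With a change over 1.3-fold required as well, 832 of all 20719 genes were higher in Wnt and 974 lower. The share of all genes at that p alone was not computed, so 3 of 26 is not read as a trait of the Wnt targets. The thresholds for this comparison were chosen after seeing the data. Genes are not independent replicates, so the p-values of Fisher's exact test overstate the evidence. The counts for independent lists also treat dim and bright genes alike. In limma 4.4% of the dimmest 25% of genes passed, against 32.7% of all genes.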

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

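The 8 lone arrays were found by a fixed rule on the gap of an array to the nearest of the other 3 in its group. The rule was applied to 230 groups of 4 arrays, where chance gives about 5%, or 11.5. It compares arrays within a group and does not use the pairing. An array apart from its group therefore need not mean a change that differs between pairs. In BIO, replicate 2 was apart for Ahrr (6.74 log2, the others 7.02 to 7.05) and Igsf11 (8.65, the others 7.81 to 7.92), replicate 3 for Cyp11b2 (3.96, the others 4.15 to 4.17) and Tiparp (10.34, the others 10.48 to 10.49), and replicate 4 for Ptch1 (9.04, the others 8.73 to 8.74). In vehicle, replicate 2 was apart for Optn (7.99, the others 8.33 to 8.37), replicate 3 for Nkd1 (5.23, the others 5.41 to 5.44) and replicate 4 for Sox9 (7.52, the others 7.42 to 7.43).

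Probe sets without a gene symbol, which no comparison above uses, also responded. In the limma fit over every probe set, 601 of the 5132 (11.7%) passed an adjusted p of 0.05, 313 higher in BIO and 288 lower, of which 28 and 37 changed at least 1.5-fold.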

How the results depend on the processing

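No alternative was added after the data were seen. Without the pair block 5023 genes passed, 5005 of them among the 6767, and the 12 list calls were kept; of the 115 selected genes 100 passed in the main fit, of which 10 lost their call and 90 kept direction and call. With the authors' paired t-test p-values after Benjamini-Hochberg adjustment 3947 genes passed (2057 higher, 1890 lower), 3705 of them among the 6767, and 15 selected genes lost their call. A gene's own spread replaces the shared spread there. Under the other settings with all pairs, 6185 to 7201 genes passed, and 7659 of all probe sets. With 1 pair left out, 5143 to 5948 genes and 12 to 13 lists passed. With cyclic loess 47.8% of calls were higher, against 52.2%. All 12 list calls were lost with an estimated correlation, leaving 0, including steroidogenesis (median −0.427, adjusted p = 0.144). The estimates for these 12 lists ran from 0.012 to 0.358. For Notch, Hedgehog and FGF/ERK targets, at 0.012 against the preset 0.01, camera's unadjusted p still went from 0.000288 to 0.0371. A higher correlation therefore does not account for every lost call. With fry 16 lists passed, including Wnt targets (median −0.12, adjusted p = 0.00886). Among the selected genes signs turned for 4, which did not pass in the main fit: Gsk3b with cyclic loess (−0.001) and, with each pair left out in turn, Gsk3b (−0.003 without replicate 1, up to 0.034), Cdkn1a (−0.045 without replicate 3 and −0.003 without replicate 4, up to 0.037), Mki67 (−0.003 without replicate 4, up to 0.075) and Pcna (0.006 without replicate 3, down to −0.055). The cause was not tested for the changes under cyclic loess, an estimated correlation, fry and the pairs left out. What signal over background limits is unknown without detection calls: 4.4% of genes in the dimmest 25% passed.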

Other observations

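The tests of splits without the pair block, of single pairs, of endoplasmic reticulum genes and of growth factor and YAP genes were chosen after the result was seen. Gpnmb, Optn, Klhl24 and Ccng2 were named after their values were seen.

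Gpnmb, a lysosomal glycoprotein, rose 3.31-fold (log2 change 1.73 ± 0.08, SE) and Optn, an autophagy receptor, 3.34-fold (1.74 ± 0.05). A hypothesis from these and Igsf11 was that targets of MITF and TFEB, factors that drive lysosome genes, rise in general. Of 22 other targets, 13 rose, 2 fell and 7 did not pass, with a median log2 change of 0.27. Camera called them as higher with the preset correlation (adjusted p = 3.38e-05) but did not call them with an estimated correlation (adjusted p = 0.212). By fry they were higher in BIO (adjusted p = 0.00247). Klhl24 fell 5.21-fold (−2.38 ± 0.06) and Ccng2, an unusual cyclin, 3.63-fold (−1.86 ± 0.06), and both are known FoxO targets. The hypothesis that FoxO targets fall was tested on 14 others, of which 8 fell and 6 did not pass, with a median of −0.25 (camera adjusted p = 0.00322; adjusted p = 0.115 with an estimated correlation; fry adjusted p = 0.000595). Fry passed 16 of the 17 lists fixed beforehand, among them the markers of cells that a cell line should lack. A pass by fry therefore says little about either hypothesis. Both remain hypotheses, found and tested on the same arrays.

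Stress response genes rose, and the question was which branch they follow. A candidate explanation is a response of ATF4, the factor that amino acid shortage and other stresses induce. Of 12 cytosolic tRNA synthetases known as ATF4 targets, 12 rose, by 0.36 to 0.80 log2. The 8 other synthetases lay between −0.03 and 0.34, 3 of them past the threshold. The medians were 0.43 apart and the means 0.41 (exact permutation test of the means over genes, two-sided, p = 1.59e-05). Genes are not independent replicates. Camera called the 12 (adjusted p = 4.95e-10; adjusted p = 0.115 with an estimated correlation) and the 8 (adjusted p = 0.0336; adjusted p = 0.311 with an estimated correlation). Within the stress list, 5 genes of the endoplasmic reticulum had a median change of 0.36 and the 11 others 0.75, a difference that did not pass (exact permutation test of the means over genes, two-sided, p = 0.061). An NRF2 response stays open. Of 10 NRF2 targets other than Slc7a11 and Nqo1, 4 rose, 1 fell and 5 did not pass, with a median of 0.02. Camera did not call them (adjusted p = 0.245), while by fry they were higher in BIO (adjusted p = 0.000595). Their median met the criterion set beforehand against such a response. Their mean was 0.11 with an SE of 0.085 over members, so a rise is not excluded.

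Wnt targets moved in both directions although BIO inhibits the kinase that restrains β-catenin. Single pairs are argued against as the source of the falls, since 9 to 11 of the 11 members that fell were still called lower with any 1 pair left out. They were also lower in the pair left out, in 39 of 39 cases, but this adds little, because a gene counts up to 4 times and the 11 had been seen to be lower in 4 of 4 pairs before the test was chosen. A fall of growth factor and YAP signals may also be involved: 10 response genes of ERK and YAP had a median change of −1.0 log2, but 4 pairs are too few to test a relation across pairs. No explanation is singled out.

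The number of genes called was compared with that of other splits of the arrays. Because same-numbered arrays deviate together, the real split is compared with the 7 other splits that part every pair. Fitted without the pair block, 1 of these 8 splits, the real one itself, called as many as 5023 genes, and the highest other called 0. In the paired fit, again only the real split, 1 of the 8, called as many as 6767, and the highest other called 0. The 8 splits are too few for a share under 0.05. The other 7 also mix BIO and vehicle arrays within each group, so a BIO difference enlarges their spread. Their 0 calls are therefore no measure of what chance gives. The 27 splits that keep at least 1 pair whole, fitted without the block, called up to 67 genes, in the split of pairs 1 and 2 against pairs 3 and 4.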
